A study of Arabidopsis thaliana with 6 samples.

How the data were processed

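RNA of dissected anthers was labelled with biotin and hybridised to Affymetrix arrays, 3 for the *myb80* mutant and 3 for wild type. Groups and replicate names were taken from the labels, which call the replicates biological. The growth protocol in the labels does not say whether the replicates were grown together, so p-values measure the spread between these samples.

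The deposited values are intensities on a linear scale, 1 per probe set and array, as judged from the values themselves. On each array the deposited intensity has a mean of 150.01 after 2% of values are trimmed at each end, a pattern that scaling every array to a common level gives. The software, background correction and summary method are not given in the sources used here. Detection calls were not used here. The median deposited intensity was 76.1, 81.1 and 64.8 in mutant replicates 1, 4 and 5-2 and 69.5, 72.8 and 73.5 in wild-type replicates 2, 5 and 6.

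By a rule fixed in advance, arrays whose medians differed by more than 0.2 on the log2 scale were shifted to a common median. The medians differed by 0.323, so each array was multiplied by 1 factor, from 0.897 to 1.12. Values were then raised to a floor of 16 and log2 transformed. Between 19.0% and 22.0% of probe sets lay at the floor on each array. Where all arrays of a group lay at the floor, a fold is a lower bound and is given as at least that fold. The 64 Affymetrix control probe sets were left out of the tests.

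Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, no covariate), and a probe set was called at adjusted p under 0.05. The main test kept all 22746 probe sets. A second test, also fixed in advance, left out the dimmest 1 in 3 probe sets by their mean over all 6 arrays, which left 15164. In the main test 1449 probe sets had a residual variance of 0 and limma's prior had 0.728 degrees of freedom; without the dimmest 1 in 3 these values were 0 and 5.39. The filter uses the mean over both groups, not the group labels.

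Both tests were run on simulated data made from these arrays, in 10 simulations with 200 probe sets changed in each. The changed probe sets were drawn only from those that the filter keeps in the real data. Residuals were shuffled among arrays and among probe sets of similar brightness. Over all 22746 probe sets, 16.6% of 4-fold and 42.8% of 8-fold changes were recovered, and 12.5% of the calls were false. Without the dimmest 1 in 3, 70.8% of 4-fold, 96.2% of 8-fold and 3.6% of 2-fold changes were recovered, and 3.66% of the calls were false. Because of this the report describes genes from the filtered test and gives the main test beside it. The simulations cannot decide between the tests, since no change was placed in the probe sets that the filter leaves out. Shuffling also removed the correlation between genes and the differences between arrays, so these rates may not hold in the real data. In these simulations camera called a shifted list of 20 probe sets in 10 of 10 and an unshifted one in 1 of 10. Genes in the simulated lists were not correlated, so this result does not bear on lists whose genes vary together.

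Probe sets were named through an annotation of the platform by gene identifiers, updated to the symbols and locus codes of NCBI RefSeq's annotation of TAIR10.1. Of 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 are unnamed here, and 13436 of those with 1 gene were matched to RefSeq. A probe set with several genes was not used for a name. Of the 311 called probe sets, 161 had 1 gene, 8 had several and 142 are unnamed here. No coordinates are given, since the files name no genome build.

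The genes named in the report follow a rule written in advance. It takes MYB80, the reported targets of MYB80, the tapetal pathway (SPL, EMS1, DYT1, TDF1, AMS and MS1), and the 10 highest and 10 lowest log2 differences among called probe sets with 1 gene whose groups do not overlap. Where nothing with 1 gene was called in a direction, it takes the 5 smallest unadjusted p. From each list it takes up to 4 called members or, with none called, up to 2 members with the smallest unadjusted p. The rule was applied to both tests. MGH3, AT5G45880, AT5G07230 and AT1G66850 were named after their values were seen.

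Of 20 gene lists fixed in advance, those with at least 3 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 9 lists. Where a gene had more than 1 probe set, the one with the highest mean over all arrays was used. The alternatives tried were the values as deposited, quantile normalization, a mean-variance trend, robust variance, array weights (statmod 1.5.0), a floor at the 20th percentile (15.8), no floor, other filters on dim probe sets, 1 probe set per gene, an adjusted p under 0.1 and leaving out each array in turn.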

Results

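Transcript levels were measured in anthers of *Arabidopsis thaliana* plants carrying a mutation in MYB80 and in anthers of wild-type plants. MYB80 is a MYB-type transcription factor of the tapetum, the cell layer that feeds the developing microspores, and plants that lack it are male sterile. Each group had 3 arrays, named in the labels as mutant replicates 1, 4 and 5-2 and wild-type replicates 2, 5 and 6. The labels do not say what the name 5-2 stands for, such as a second extraction or hybridisation, and the array was counted as a replicate of its own. Per the labels, about 1000 anthers of stages 5 to 8 were dissected for each biological replicate, a span that runs from pollen mother cells to released microspores. Each array gave 1 intensity for each of 22810 probe sets, of which 64 were Affymetrix controls and 22746 were tested. The number of arrays limits the precision of every comparison.

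The arrays resembled each other within and between groups. Pearson's r of log2 values, across probe sets within a pair of arrays, ran from 0.911 to 0.938 between mutant arrays, from 0.936 to 0.948 between wild-type arrays and from 0.880 to 0.919 between the groups. Of the 22746 deposited values compared exactly, at most 1 was identical in any pair of arrays. The ratio of the 3' to the 5' actin control probe set, a sign of RNA integrity, was 20.3, 29.6 and 17.1 in mutant replicates 1, 4 and 5-2 and 24.8, 22.5 and 13.3 in wild-type replicates 2, 5 and 6, so the groups overlapped. The same ratio for GAPDH ran from 2.39 in mutant replicate 5-2 to 4.57 in wild-type replicate 6. Every array thus had a large excess of 3' signal for actin, and the overlap does not show that the RNA was intact.

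The comparison of mutant with wild-type anthers asks which transcripts differ in level at these stages. Anthers hold several cell types, so a difference need not mean that MYB80 controls the gene. It may also reflect the mix of cells or the mean stage of the anthers, which the comparison cannot tell apart from control by MYB80. THI2.1 and AT5G66390 were over 11-fold higher in the mutant, and AT4G35670 and AT5G42170 were over 17-fold lower. With the dimmest 1 in 3 probe sets left out, limma with Benjamini-Hochberg adjustment found 68 probe sets higher and 243 lower among 15164 tested, at adjusted p under 0.05. With low values raised to the floor, the folds ran from 2.43 to at least 15.99 among those that rose and from 2.32 to at least 22.3 among those that fell, and in no called probe set did the mutant and wild-type arrays overlap. Over all 15164, the groups did not overlap in 17.3% of probe sets, where chance gives 10%. The words rose and fell below refer to this test.

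The test named as the main one before the data were examined kept all 22746 probe sets and called only 3. These were AT5G60070, at least 5.14-fold lower (adjusted p = 0.0229), and a pair of probe sets with no gene name in the table used here, at least 9.92-fold lower (adjusted p = 0.043) and at least 15.99-fold higher (adjusted p = 0.0481). All 3 were also among the 311 calls of the filtered test, which had also been fixed in advance and was given the lead after both counts were seen. At unadjusted p under 0.05 the unfiltered test had 1038 probe sets higher and 1275 lower. None of the other genes described below passed the unfiltered test, in which THI2.1 had an adjusted p of 0.123 and AT4G35670 one of 0.133.

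Among the probe sets that rose and name 1 gene, that of THI2.1, which encodes a thionin, an antimicrobial peptide, had the largest difference, from a geometric mean intensity of 438 in wild type to 6962 in the mutant (15.9-fold, log2 difference 3.99 ± 0.42, SE, n = 3 per group, limma adjusted p = 0.0046). AT5G66390, which encodes the peroxidase PRX72, was 11.8-fold higher (log2 difference 3.56 ± 0.43, adjusted p = 0.00696); 2 of its 3 wild-type arrays stood at the floor, so this fold understates the difference. AT1G04645, a member of the self-incompatibility S1 protein family, was 11.7-fold higher (3.55 ± 0.58, adjusted p = 0.0218), and AT3G48450 was 11.1-fold higher (3.48 ± 0.29, adjusted p = 0.00272). The lipid transfer protein genes AT5G52160 and AT3G07450 were 8.66-fold and 4.97-fold higher, and AT3G07450 was bright in both groups, at 13550 in the mutant and 2727 in wild type. The F-box protein gene AT3G23880 was 6.02-fold higher, AT3G25260 was 5.50-fold higher and AT3G57950 was 5.04-fold higher. AT2G11150 was at the intensity floor on all 3 wild-type arrays and was at least 5.03-fold higher. The unfiltered test's rule for its highest genes also named AT3G47510 and AT1G52310, with log2 differences of 1.70 and 0.67 that did not pass there (adjusted p = 0.109 for each).

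Among the genes that fell, the pectin lyase-like gene AT4G35670 was 22.1-fold lower (log2 difference -4.47 ± 0.46, SE, n = 3 per group, limma adjusted p = 0.0046), and a second gene of that fold, AT5G48140, was 15.7-fold lower (-3.97 ± 0.81, adjusted p = 0.0431). AT5G07430, a pectinesterase gene, was 20.01-fold lower (-4.32 ± 0.87, adjusted p = 0.041). AT3G23770 and AT5G64790, both glucanase-family glycosyl hydrolase genes, were 19.4-fold and 16.01-fold lower, with adjusted p of 0.049 and 0.00888. The lipase-family gene AT5G42170 was 17.7-fold lower (-4.15 ± 0.48, adjusted p = 0.00629). AT4G02250 was 18.3-fold, AT3G01250 17.8-fold, AT5G61720 16.6-fold and AT1G71680 15.9-fold lower. In most of these genes at least 1 mutant array stood at the floor of 16, so the folds understate the difference.

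**Figure D1:**
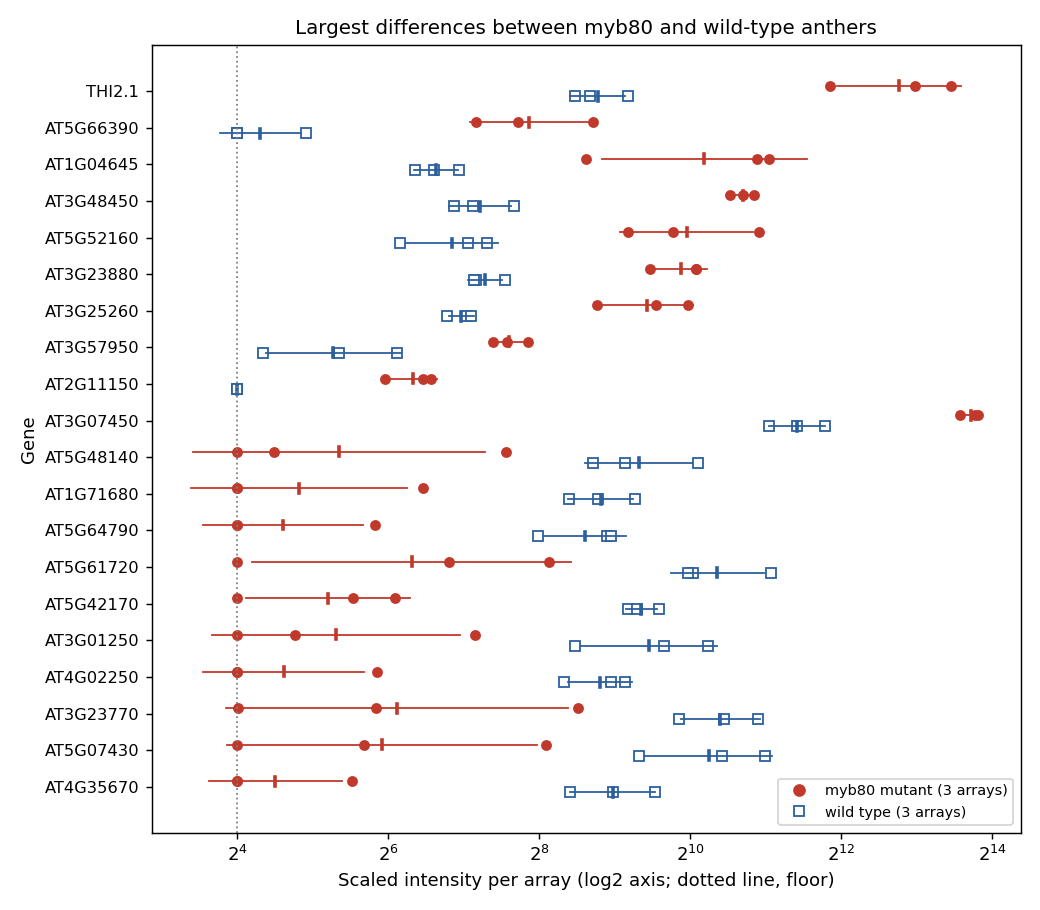
Scaled intensity on a log2 axis for 10 genes that rose and 10 that fell, with 1 point per array (filled circles for myb80 mutant, open squares for wild type). These genes have the largest differences among called probe sets that name 1 gene and whose groups do not overlap. Each group has a tick at its mean and a line of 1 SD either side of it on the log2 scale. A dotted line marks the floor of 16. In each gene the 3 mutant arrays lie on one side of the 3 wild-type arrays, and THI2.1 has the largest mean difference of the 10 plotted genes that rose, 15.9-fold.

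The size of these lists depended on single arrays. Leaving out mutant replicate 4 gave 117 higher and 418 lower, while the totals without mutant replicates 1 and 5-2 were 168 and 45, and those without wild-type replicates 2, 5 and 6 were 63, 43 and 86; 32 of the 311 calls passed in all 6 of these tests, 10 higher and 22 lower. The 32 included THI2.1, AT5G66390, AT3G48450, AT3G23880, AT2G11150, AT3G07450, AT4G35670, AT4G02250, AT5G42170 and AT5G60070, whereas AT5G07430, AT3G23770, AT3G01250 and AT5G48140 passed in 1 of the 6, AT1G04645, AT3G57950 and AT5G61720 in 2, AT5G52160, AT3G25260 and AT1G71680 in 3, and AT5G64790 in 4. On the intensities as deposited, 54 were higher and 87 lower, which raised the share of higher calls from 21.9% to 38.3%.

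The mutated gene itself could not be followed, since no probe set carries MYB80 in the probe table used here, and its level was not analysed here. The labels were therefore not checked on the mutated gene. Of the regulators around MYB80 in the tapetal pathway, DYT1, TDF1 and MS1 were likewise not analysed here. SPL, which acts early in anther cell specification, differed by -0.04 ± 0.27 on the log2 scale (SE, limma adjusted p = 0.981). EMS1, a receptor kinase for tapetal identity, differed by 0.63 ± 0.31 (adjusted p = 0.47). AMS, a basic helix-loop-helix factor of tapetum development, was 2.42-fold higher in the mutant, with all 3 mutant arrays above all 3 wild-type arrays, but did not pass the filtered test (log2 difference 1.28 ± 0.38, adjusted p = 0.148). AMS passed in 1 of the 6 filtered tests that left out an array, the one without mutant replicate 4 (adjusted p from 0.0239 to 0.375).

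Of 3 genes that the literature reports as direct targets of MYB80, only UNDEAD, an aspartic protease gene (symbol UND), had a named probe set of its own. It fell 8.88-fold, from a geometric mean of 729.5 in wild type to 82.1 in the mutant (log2 difference -3.15 ± 0.63, SE, n = 3 per group, limma adjusted p = 0.0406). Its adjusted p was 0.314 in the unfiltered test, and it passed in 2 of the 6 tests that left out an array, with adjusted p from 0.0203 to 0.159. VGD1, another of the 3, shares a probe set with VGDH1. That probe set was 15.8-fold lower in the mutant and did not pass the filtered test (limma adjusted p = 0.104). These targets may have been chosen on these same arrays, in which case the fall of UNDEAD is not independent evidence of its direction, and neither is that of this probe set.

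Gene lists fixed in advance were tested as sets with limma's camera over all probe sets, with a preset correlation between genes of 0.01, where at least 3 members had a named probe set. This held for 9 of 20 lists. Together the lists held 254 distinct genes, most of which had no named probe set, and the others were measured by 57 distinct probe sets. All 9 measured entries of the microspore and pollen list were lower in the mutant, with a median log2 difference of -2.21 (camera adjusted p = 5.23e-07, and adjusted p = 0.148 with an estimated correlation). In the filtered test 2 of the 9 fell when adjusted over all 15164 probe sets, and 9 fell when adjusted over the list alone; in the unfiltered test these counts were 0 and 2. ACT12, a pollen actin gene, fell 6.51-fold (log2 difference -2.70 ± 0.50, limma adjusted p = 0.0328), and AGL104, a MADS-box gene of pollen maturation, fell 4.63-fold (-2.21 ± 0.33, adjusted p = 0.0171). Of the 6 filtered tests that left out an array, ACT12 passed in 1 (the one without mutant replicate 4; adjusted p up to 0.14) and AGL104 in 3 (adjusted p from 0.00908 to 0.0824). MGH3, a histone gene of the male germline, had a log2 difference of -2.43 ± 0.67 and did not pass the filtered test (adjusted p = 0.119). AT5G45880, a homologue of the tomato pollen gene LAT52, had one of -4.10 ± 1.08 (adjusted p = 0.105). One entry is the probe set shared by VGDH1 and VGD1, a reported target of MYB80, and was counted once. That target may have been chosen on these same arrays. The list holds markers of microspores and pollen, and the geometric mean intensities of its 9 entries in wild type ran from 71.6 to 6590. Fewer microspores or a younger mean stage in the mutant anthers could also lower them, and neither was tested.

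All 4 measured genes of the tapetal lipid transfer protein list were higher in the mutant, with a median log2 difference of 1.54 (camera adjusted p = 3.54e-05, and adjusted p = 0.148 with an estimated correlation). In the filtered test 2 rose when adjusted over all 15164 probe sets and 4 when adjusted over the list alone; in the unfiltered test these counts were 0 and 3. AT5G52160 rose 8.66-fold (log2 difference 3.11 ± 0.47, limma adjusted p = 0.0172), and AT5G62080 rose 3.48-fold, from 3238 to 11270 (1.80 ± 0.32, adjusted p = 0.0277). Of the 6 filtered tests that left out an array, AT5G52160 passed in 3 (adjusted p from 0.00454 to 0.074) and AT5G62080 in 1, the one without mutant replicate 4 (adjusted p from 0.0166 to 0.11). AT5G07230 and AT1G66850 had log2 differences of 1.28 ± 0.46 and 0.80 ± 0.25, with adjusted p of 0.273 and 0.186.

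Of 7 measured tapetum regulators, 6 were higher in the mutant, with a median log2 difference of 0.63 (camera adjusted p = 0.00644, and adjusted p = 0.148 with an estimated correlation). None passed the unfiltered test or the filtered one, and in the filtered test only AMS, of 5 tested there, passed when adjusted over the list alone. ROXY2, a glutaredoxin gene of anther development, had a log2 difference of 1.23 ± 0.41 in the unfiltered test (adjusted p = 0.422). By fry, which asks whether a list's genes move one way on balance, adjusted p was 0.0465 for the microspore and pollen list, 0.026 for the lipid transfer proteins and 0.0602 for the regulators.

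The other 6 lists tested as sets were not called. In the cell death and protease list, with 9 measured members, UNDEAD fell and 6 others tested did not pass (camera adjusted p = 0.463). No member passed in the pollen coat and tapetosome list, where ATA27 differed by -0.69 ± 0.33 (camera adjusted p = 0.463), or in exine patterning, where AT1G33430 (KNS4) differed by 0.58 ± 0.27 and SWEET8 by -0.10 ± 0.26 (camera adjusted p = 0.463). None passed in the sugar supply list, where SWEET14 had a log2 difference of -2.29 ± 0.57 (limma adjusted p = 0.0856) and SWEET13 one of -0.35 ± 0.39 (camera adjusted p = 0.205); adjusted over the list alone 1 fell. The 7 measured meiosis genes had a median of -0.18 and a mean of -0.02, opposite in sign to the upward direction that camera gave (adjusted p = 0.984).

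Apart from the microspore and pollen list, no measured marker of other cells and tissues that dissected anthers could carry was called. Few were measured: 7 of 26 meiosis genes, 3 of 11 sepal, petal and carpel markers and 2 of 22 photosynthesis genes. For handling and heat stress it was 1 of 11, and for cell division 2 of 16. Even in the simulations the filtered test recovered only 3.6% of 2-fold changes, so differences of that size could be missed. Of the meiosis genes, ATMND1 differed by 0.65 ± 0.28 (limma adjusted p = 0.386), and SPO11-2, tested only without the filter, by -0.95 ± 0.37 (adjusted p = 0.504). Among the sepal, petal and carpel markers, INO differed by 0.55 ± 0.34 and SPT by 0.09 ± 0.26 (camera adjusted p = 0.463). The photosynthesis genes LHCB4.1 and RCA differed by 0.86 ± 0.33 and 0.58 ± 0.30 (limma adjusted p = 0.31 and 0.502). The stress gene STZ, also called ZAT10, differed by 0.38 ± 0.27, and the mitotic kinase genes AUR1 and AUR2 by -0.33 ± 0.27 and -0.08 ± 0.29 (adjusted p = 0.655, 0.723 and 0.962). Outside these marker lists, SHT, which makes tapetal spermidine conjugates, differed by -0.41 ± 0.29 (adjusted p = 0.667). The flavonoid gene DFR, tested only without the filter, differed by -0.60 ± 0.62 (adjusted p = 0.798). The lists of sporopollenin synthesis, callose and tetrad separation, endothecium and secondary wall, jasmonate, and cuticular wax and cutin had no member with a named probe set and were not analysed here.

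**Figure D2:**
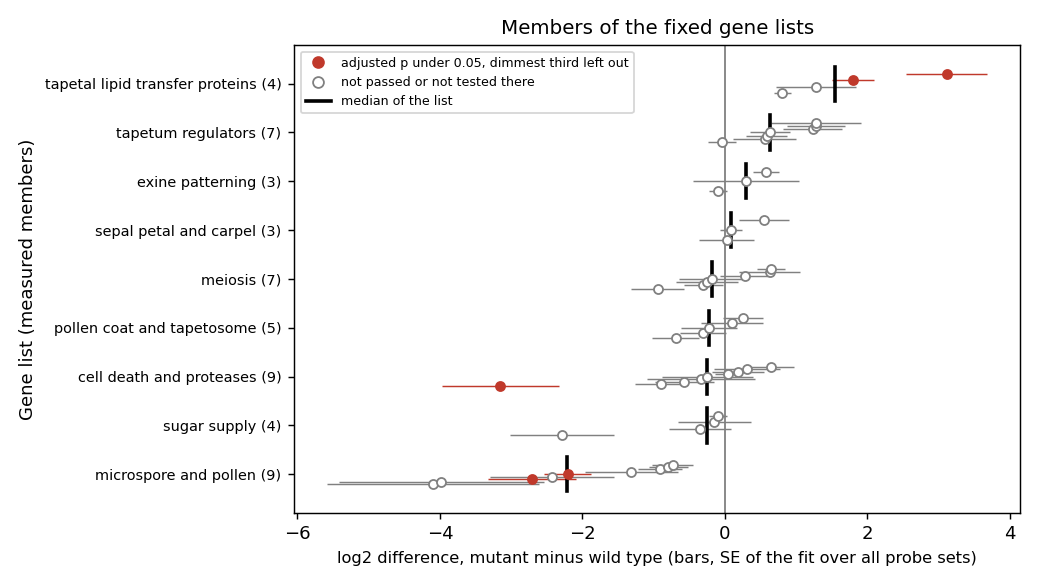
Log2 difference, mutant minus wild type, of each measured member of the 9 lists tested as sets, with the number of members in brackets, bars of 1 SE from the test over all probe sets, black lines at list medians, and red points for members with adjusted p under 0.05 without the dimmest 1 in 3 probe sets. All 9 microspore and pollen entries lie below 0, with a median of -2.21, and all 4 lipid transfer protein genes lie above 0, with a median of 1.54.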

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

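The test in this part was chosen only after the result was seen. Among the Affymetrix control probe sets, which were left out of the tests between groups, AFFX-r2-At-U12639_at was bright on all 3 mutant arrays, from 2982 to 7713 in scaled intensity, and dim on all 3 wild-type arrays, from 13.4 to 29.7. It was singled out because the lowest mutant array lay 100.4-fold above the highest wild-type array. Unequal amounts of spiked hybridization controls are argued against by the 18 bacterial and phage control probe sets, whose median log2 difference was -0.00117, with a range from -0.23 to 0.19. What stays open is that the probe set may detect a sequence carried by the mutant line alone, such as part of an inserted construct, or that it cross-hybridises with a transcript that differs between the lines; what it was designed against is not given in the sources used here, and neither was tested. The labels could not be checked on MYB80, which has no named probe set here. On the arrays labelled mutant, UNDEAD was 8.88-fold lower and the microspore and pollen list had a median log2 difference of -2.21. UNDEAD is not an independent check of the labels, since the reported targets may have been chosen on these same arrays. The list also includes a reported target, VGD1, in a shared probe set.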

How the results depend on the processing

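The alternatives that combine the filter with another choice, no floor, and leaving out probe sets at the floor on all arrays were chosen after the data were seen; the others were planned. No paired analysis was possible because the mutant replicates (1, 4 and 5-2) and the wild-type replicates (2, 5 and 6) share fewer than 2 numbers.

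Over all probe sets, the counts of 1 higher and 2 lower became 0 and 0 with a mean-variance trend, 0 and 1 with robust variance or 1 probe set per gene, 2 higher with quantile normalization, 1 lower with no floor, and 2 and 8 at adjusted p under 0.1 (7 of the 8 at least 2-fold). Leaving out probe sets at the floor on all arrays gave 8 and 21, and leaving out the dimmest 1 in 3 gave 68 and 243. Leaving out 1 array gave 0 to 3 higher and 0 to 4 lower. Apart from the 7 these counts were the same with a 2-fold limit. Where a count was 0, the unadjusted counts given in the report apply to the main setting only.

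Without the dimmest 1 in 3, the counts of 68 higher and 243 lower became 54 and 87 on the values as deposited, 61 and 137 with quantile normalization, 118 and 409 with a mean-variance trend, 154 and 496 with array weights (494 at least 2-fold), 23 and 47 with no floor, 29 and 111 with 1 probe set per gene, and 133 and 408 at adjusted p under 0.1 (132 at least 2-fold higher). Robust variance gave 63 and 210, and a stricter filter on dim probe sets gave 94 and 296. Leaving out 1 array gave 12 to 117 higher and 31 to 418 lower, the most without mutant replicate 4 and the fewest without wild-type replicate 5. With 1 probe set per gene fewer probe sets are tested; for the other settings the cause was not tested. No called probe set that a setting tested changed sign there, and all 311 were tested except with no floor (284), with the stricter filter (216) and with 1 probe set per gene (161). Of 311 calls, 141 were shared with the values as deposited, 192 with quantile normalization and 275 without mutant replicate 4. Of 25 genes named by the rule and called, 18 were still called on the values as deposited, 19 with quantile normalization and 10 with no floor, where 2 were not tested; 24 were without mutant replicate 4, 19 without mutant replicate 1, 15 without wild-type replicate 6, 12 without wild-type replicate 2, and 10 without mutant replicate 5-2 or wild-type replicate 5.

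With an estimated correlation, camera's adjusted p was 0.148 for the microspore and pollen list, 0.148 for the tapetal lipid transfer proteins and 0.148 for the tapetum regulators, so none of these calls held. The estimated correlations were 0.386, 0.401 and 0.00389, in that order. For the regulators the estimate lay below the preset 0.01, so a higher correlation between genes does not account for the loss of that call. By fry the regulators had 0.0602 in one direction and 0.0772 in either. Under the scaling, trend, filter, floor, weight and single-array settings the 3 lists stayed under 0.05; without 1 array their adjusted p ran from 2.03e-08 to 0.000446, from 3.08e-05 to 0.000729 and from 0.000251 to 0.0432, in that order. In all, 148 of the list results kept their side of the threshold and 5 lost it. Robust variance was not run for the lists, since camera does not use it, and no setting could be run for MYB80, which has no named probe set here. Of the probe sets, 19.0% to 22.0% lay at the floor on each array, where differences are bounds.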

Other observations

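The tests on mutant replicate 4 and the counts of splits were chosen after the results were seen; those on the chromosomal position of called genes and on symbol families were not. The genes in the next 2 paragraphs were named after their values were seen.

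Further genes fell in the filtered test. ANX2, a receptor-like kinase that keeps the pollen tube intact, was at the floor on all 3 mutant arrays and at least 5.12-fold lower (log2 difference -2.36 ± 0.31, limma adjusted p = 0.0109), and RALFL26, a gene for a small signalling peptide, was 9.95-fold lower (-3.31 ± 0.64, adjusted p = 0.0366). AtVEX1, also named SWEET5, a sugar transporter gene of the pollen vegetative cell, was 6.35-fold lower, and CHX19, a cation exchanger gene, 6.68-fold lower. The subtilase gene SBT4.13 was 14.8-fold lower (-3.88 ± 0.34, adjusted p = 0.00278), and the polygalacturonase gene ADPG1, the expansin gene EXPA24 and the cellulose-synthase-like gene CSLC12 were 4.42-fold, 5.00-fold and 5.96-fold lower. XIC, a myosin gene, was 4.61-fold lower, and UGT78D2, a flavonoid glucosyltransferase gene, 2.84-fold lower. RALFL26 and EXPA24 were at the floor on 2 of 3 mutant arrays, so their folds understate the difference. SBT4.13 and CSLC12 passed in all 6 tests that left out an array, ANX2 in 5, ADPG1 in 3, XIC in 2, and RALFL26, AtVEX1, CHX19, EXPA24 and UGT78D2 in 1.

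Further genes that rose include 3 of the SWEET sugar transporters. SWEET3 was 4.51-fold higher (log2 difference 2.17 ± 0.30, adjusted p = 0.0119), SWEET7 3.11-fold higher (1.64 ± 0.31, adjusted p = 0.0352) and SAG29, also named SWEET15, 3.87-fold higher (1.95 ± 0.41, adjusted p = 0.0494). WES1, also named GH3.5, was 3.68-fold higher (1.88 ± 0.36, adjusted p = 0.0362). Of the 6 tests that left out an array, SWEET3 passed in 3, and SWEET7, SAG29 and WES1 in 1. Whether genes that share a symbol family were called together more often than chance was tested over 31 families in both directions, 62 Fisher's exact tests in all. The smallest adjusted p was 0.063, for 2 called of 12 tested genes with a SWEET symbol, so no family passed; SAG29 and AtVEX1, which carry other symbols, were not counted in it.

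Mutant replicate 4 lay between the other mutant arrays and wild type. On the first principal component of the filtered probe sets, which held 44.9% of the variance, it scored -7.58, against -55.9 and -53.4 for mutant replicates 1 and 5-2 and 27.7 to 50.6 for wild type. An error in the scaling of the array would move risen and fallen genes the same way. Its deviations went opposite ways, by -2.42 on the log2 scale for risen minus fallen genes, both chosen without this array. Scaling alone would therefore not give this pattern. Genes chosen without an array may also lie nearer wild type on it through that choice, so an added scaling error is not excluded. Wild-type RNA mixed into it should give a single share from both sets. The median share was 28.2% from 418 fallen probe sets (95% bootstrap interval 25.3 to 30.8). It was 63.8% from 117 risen ones (58.6 to 70.0), a difference of 35.7 percentage points. These intervals describe the spread over probe sets of 1 array, whose levels can vary together, and not the spread between arrays. The intervals stayed apart against mutant replicate 1 alone (28.1% and 56.9%) and 5-2 alone (27.6% and 69.9%), but this does not exclude admixture, since on the same genes those arrays set against each other also gave unequal shares, 31.2 points apart for mutant replicate 1 and 43.2 for 5-2. Admixture, anthers of another mean stage and variation between plants may each account for the position of mutant replicate 4, and the last 2 were not tested.

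Genes near MYB80 could differ because the mutant line carries another chromosome segment there. Only 1.89% of the called genes, 3 of 159, lay within 300 gene models of the MYB80 locus on either side, against 2.32% of the tested genes (190 of 8179; Fisher's exact test, two-sided, p = 1, odds ratio 0.806 with a 95% interval from 0.163 to 2.43). Differences within this window could therefore not account for most of these 159 genes. A longer segment and differences in background elsewhere in the genome were not tested. Called probe sets with no gene or several genes were not placed.

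The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. Over all probe sets, 5 of the 10 splits gave at least the 3 calls of the real one, and the highest other split gave 5. Without the dimmest 1 in 3 probe sets, 1 of the 10 splits, the real one, gave its 311 calls, and the highest other split gave 0. Every other split puts mutant and wild-type arrays in the same group, which widens the spread within groups if the real groups differ. Few calls in those splits are therefore no measure of what chance gives.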
